A study of Mus musculus with 2 samples.

How the data were processed

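Single-cell RNA was measured in 2 libraries of hippocampus from 5xFAD mice, 1 per group, labelled as AAV9-GFAP::NeuroD1-P2A-GFP and AAV9-GFAP::GFP. Per the labels' protocols, fresh hippocampus was dissociated with papain, cells were loaded into a SCOPE-chip with microwells, and bead-captured mRNA was reverse transcribed, amplified and made into Illumina libraries; the description field of the labels names another single-cell platform, and which of them was used is not settled here. The deposited matrices hold UMI counts, as whole numbers per gene and barcode, and the authors named FastQC, fastp, cutadapt, STAR and featureCounts and genome build mm39, without versions or roles, per the submitters' processing notes. The annotation release is not given in the sources used here. The gene lists pair Ensembl mouse identifiers with symbols for 53717 features, including 2 vector features named ND1 and GFP. The reference given for this work was of another build, so no coordinates are printed. Barcodes in the files start at 500 UMIs in both libraries.

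Cells with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, which removed 131 barcodes of the NeuroD1 library and 104 of the GFP library. Scrublet in scanpy then called 509 (3.84%) and 570 (4.90%) of the remaining cells doublets, and these were removed. Counts were scaled to 10000 per cell, log1p transformed, and clustered jointly on 3000 variable genes without mitochondrial, ribosomal, haemoglobin, sex-linked and immediate early genes and Neurod1, with 30 principal components, 15 neighbours and Leiden at resolution 1.0 with fixed seeds. The 32 clusters were named as "X-like" classes from markers fixed before the data were examined, with at least 3 markers detected among the leading genes, which gave 13 named classes and 5 unnamed clusters. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Haemoglobin genes made up 0.462% of UMIs in kept cells of the NeuroD1 library and 0.001% in the GFP library, mitochondrial genes 3.07% and 4.30%, and ribosomal protein genes 2.25% and 5.31%.

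No test between groups is possible with 1 library per group. Raw counts were summed per library and class. CPM values are scaled to the UMI total of the class sum in that library and have an exact Poisson 95% interval; a ratio of CPM has an exact conditional binomial 95% interval, and a share of cells a Clopper-Pearson 95% interval. Where 1 library had 0 UMIs, a ratio is given as "at least" the end of its interval nearest to 1. A list's log2 ratios (0.5 UMI added to each sum) over members with at least 20 UMIs in both sums together gave the median, its order-statistic interval, and the percentile among 10000 random lists matched on mean expression. The 24 gene lists and the classes each is read in were fixed before the data were examined. Genes were named by rule: in each class with at least 100 cells per library, among genes with at least 50 UMIs in 1 sum and a CPM at least 25% of the highest class, ranked by the interval end nearest to 1, the 10 highest and 10 lowest in the astrocyte-like class and up to 6 of each in other classes, leaving out mitochondrial, ribosomal, haemoglobin, sex-linked and Gm- or Rik-named genes; list members, Neurod1, Gfap, App and Thy1 could be named too, and some genes that the rule allows are not reported here. Xist, Ddx3y and the Ttr and haemoglobin levels were chosen as measures of the libraries. Thinned values draw 500 UMIs per cell, and no cell was left out.

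The interval and list procedures were tested on simulated counts made from the real class sums of both libraries over 53717 genes. In astrocyte-like and microglia-like simulations, intervals of all 50 genes per fold size lay on the right side of 1. They held the true value for 94.6% and 93.7% of unchanged genes and 95.5% and 95.0% of changed genes. Median estimated ratios were 0.26 and 0.24 for 0.25, 0.48 and 0.47 for 0.5, 1.94 and 1.98 for 2 and 3.89 and 3.87 for 4. These simulations hold no difference between animals, which the data cannot measure. Genes scored in them had a higher minimum UMI sum than list members and named genes, so intervals at lower counts were not tested. Counts were drawn as Poisson, so UMIs crowded in a few cells were not simulated. Alternatives covered cell filters, doublets, clustering, scaling, low counts, thinning, the weight of cells and free RNA, and their effect is given at the end.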

Results

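The data were single-cell RNA counts from the hippocampus of 5xFAD mice, a transgenic strain that develops amyloid plaques. The mice had received an AAV9 vector with a GFAP promoter, which is active mainly in astrocytes. In the NeuroD1 group the vector carried Neurod1, a proneural transcription factor, together with GFP, and in the GFP group it carried GFP alone. Each group was 1 library, and the series text gives 3 mice per group and 3 weeks after injection. A time of 6 months is recorded for both groups. The NeuroD1 library held 13402 barcodes and 51236521 UMIs, and the GFP library held 11739 barcodes and 17504950 UMIs. After filtering, 12762 and 11065 cells remained, with medians of 2555 and 1170 UMIs per cell. There was no replicate in either group, so no test between groups was made, and the 95% intervals given with counts, shares and ratios cover counting error only. The libraries also differed in sex-linked RNA: Xist, transcribed from the inactive X chromosome, was at 0.039 CPM in the NeuroD1 library and 105 CPM in the GFP library, and the Y-linked Ddx3y was at 69.6 and 0.057 CPM. Ttr, the transthyretin RNA of the choroid plexus, made up 12.97% and 2.24% of UMIs. In astrocyte-like cells, which are not its source, Ttr was at 10310 CPM in the NeuroD1 library and 2169 CPM in the GFP library.

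The series title concerns conversion of astrocytes to neurons, so the delivered RNA was examined first. Among the named classes, vector GFP was most abundant in astrocyte-like cells of both libraries and far lower in the NeuroD1 library. It had 552 UMIs (46.9 CPM) in astrocyte-like cells of the NeuroD1 library and 19316 UMIs (6569 CPM) in those of the GFP library, which is 140-fold lower (interval 129 to 153). A GFP UMI was present in 225 of 3670 astrocyte-like cells (6.13%, interval 5.38 to 6.96) and in 1343 of 2147 (62.6%, interval 60.5 to 64.6). Microglia-like cells, which should lack the promoter's activity, had a GFP UMI in 0.0820% and 6.32% of cells at medians of 1811 and 1317 UMIs per cell, against medians of 2466 and 1150 in astrocyte-like cells. Thinning every cell to 500 UMIs gave astrocyte-like shares of 1.20% and 50.6%, and moved the ratio of GFP CPM from 0.00713 to 0.00437. The vector feature named ND1 had 0 UMIs in both libraries, so it measured no vector RNA. Neurod1 (ENSMUSG00000034701) was concentrated in immature neuron-like cells, at 993 CPM (330 UMIs) in the NeuroD1 library and 1298 CPM (77 UMIs) in the GFP library, where it was 0.765 times as high in the NeuroD1 library (interval 0.595 to 0.994). In astrocyte-like cells Neurod1 had 19 and 2 UMIs, a CPM ratio of 2.37 with an interval of 0.572 to 21.0. A vector transcript whose counted end lies outside the mouse gene would not add to the Neurod1 count. Neither feature therefore checked which library received the NeuroD1 vector, and the labels were used as given.

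**Figure D1:**
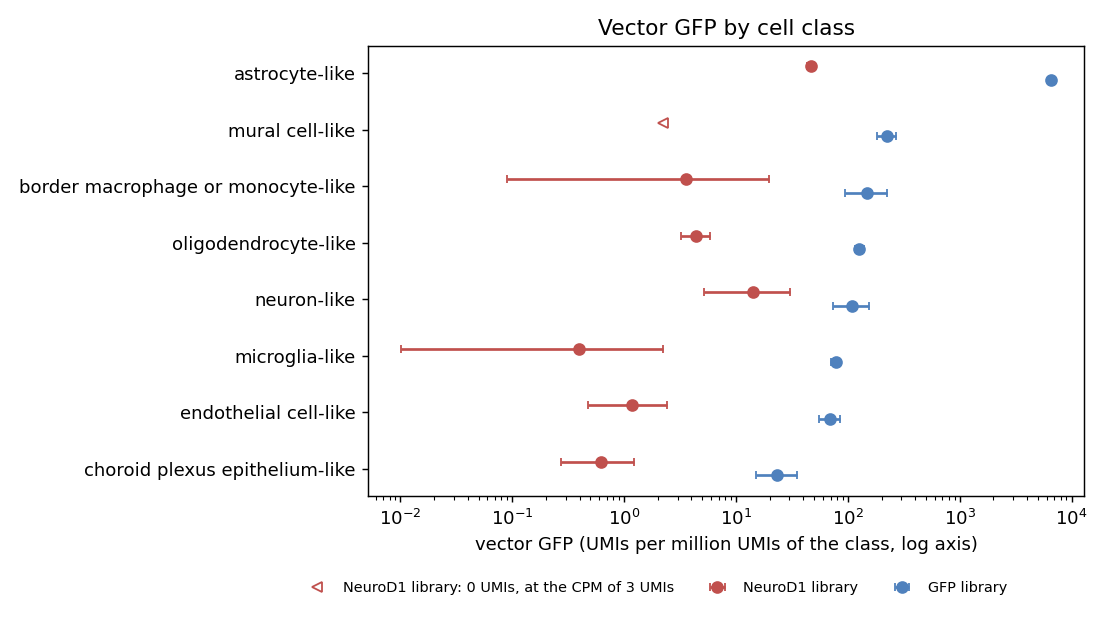
Vector GFP in CPM of each cell class sum (log axis) in the NeuroD1 and GFP libraries, with exact Poisson 95% intervals as bars and an open triangle at the CPM of 3 UMIs where the count was 0. Astrocyte-like cells had 46.9 CPM in the NeuroD1 library and 6569 CPM in the GFP library.

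Cell class shares differed between the libraries for most classes. Microglia-like cells, the resident immune cells of the brain, were 9.55% of kept cells in the NeuroD1 library and 33.0% in the GFP library, a ratio of 0.289 (interval 0.271 to 0.309). Astrocyte-like cells were 28.8% and 19.4% (ratio 1.48, interval 1.41 to 1.56), and endothelial cell-like cells were 15.9% and 9.15% (ratio 1.74, interval 1.62 to 1.88). Choroid plexus epithelium-like cells, which make cerebrospinal fluid, were 6.60% and 1.39%. Immature neuron-like cells, led by Igfbpl1, Sox11 and Calb2, were 117 cells (0.917%) and 37 cells (0.334%), a ratio of 2.74 (interval 1.88 to 4.08). A higher share was not particular to this small class. Ratios were 2.84 (interval 1.91 to 4.33) for oligodendrocyte precursor-like and 3.65 (interval 2.40 to 5.73) for fibroblast-like cells. For T or NK lymphocyte-like cells the ratio was 0.409 (interval 0.295 to 0.562). Oligodendrocyte-like cells were 24.7% and 20.6% (ratio 1.20). Neuron-like cells were 1.32% and 1.72% (ratio 0.771, interval 0.623 to 0.954). Both of these directions turned with processing: the neuron-like ratio was 1.22 with at most 10% mitochondrial UMIs per cell, and the oligodendrocyte-like ratio was 0.865 as a share of cells outside the choroid plexus, microglia-like and unnamed cells. Neuron-like cells came from different clusters: cluster 18, led by the Cajal-Retzius gene Reln, held 162 and 72 cells, and cluster 24, led by Thy1 and the glutamate transporter Slc17a7, held 7 and 118 cells. Dissociation with papain precedes all these shares and unnamed clusters held 2.58% and 7.10% of cells.

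**Figure D2:**
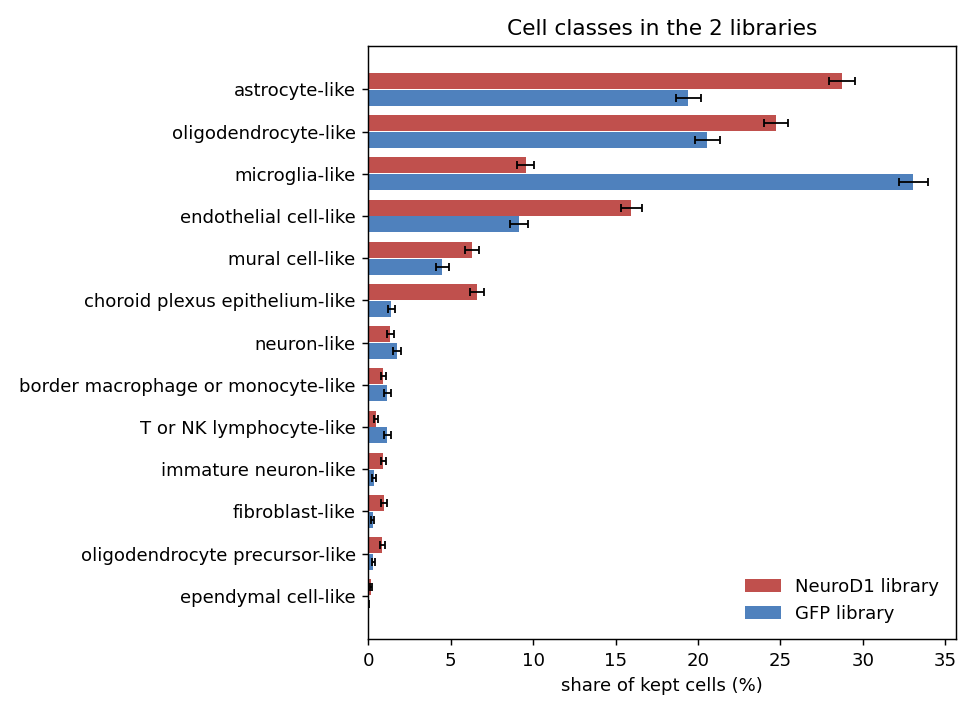
Share of kept cells (%) in each named cell class of the NeuroD1 and GFP libraries, with exact Clopper-Pearson 95% intervals as bars. Microglia-like cells were 9.55% and 33.0%, and astrocyte-like cells 28.8% and 19.4%.

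Astrocyte-like cells were then read for neuronal RNA. Members of the proneural and immature neuron list, genes switched on when progenitors become neurons, had a median log2 CPM ratio (NeuroD1 over GFP library) of 0.31 (order-statistic interval over members 0.09 to 0.96), above 98.89% of matched random lists. Of its 18 measured members, 8 were at least 1.5-fold higher and 2 at least 1.5-fold lower. Sox11 (82 and 5 UMIs) was 4.09-fold higher (interval 1.68 to 12.9) and Igfbpl1 (63 and 2 UMIs) 7.86-fold higher (interval 2.09 to 66.3), while Gadd45g, a growth arrest gene, was at 173 and 599 CPM. Only 1 of the 18 members, Rnd2, reached 25% of its highest class. Sox11 was at 6.96 and 1.70 CPM in astrocyte-like cells against 816 and 641 CPM in immature neuron-like cells, and Igfbpl1 at 5.35 and 0.680 CPM against 2344 and 1871 CPM. In the NeuroD1 library Sox11 had 0 UMIs in oligodendrocyte-like and microglia-like cells (upper limits 0.350 and 1.47 CPM), 6 UMIs in endothelial cell-like cells (upper limit 2.18 CPM) and 2 UMIs in choroid plexus epithelium-like cells (upper limit 0.564 CPM). Igfbpl1 had 10 UMIs (upper limit 1.75 CPM), 1 UMI (2.22 CPM), 8 UMIs (2.63 CPM) and 45 UMIs (4.70 CPM) in the same order of classes. Free RNA shared alike by all classes would reach these classes too, so it is not the whole source of Sox11 in astrocyte-like cells. There Sox11 was spread over 73 cells of the NeuroD1 library, while 10 cells held 58 of the 63 Igfbpl1 UMIs. The mature neuron and synapse list had a median of 0.13 (-0.49 to 0.34), above 99.02% of random lists, with 5 of 25 members at least 1.5-fold higher and 5 lower. Only 2 of these 25 members reached 25% of their highest class. The median changed side to -0.12 over members with at least 5 UMIs, -0.17 thinned and -0.22 as a mean over cells. No direction is read from this list. With every cell at 500 UMIs, at least 1 UMI of the proneural list was present in 23.2% of astrocyte-like cells of the NeuroD1 library and 32.2% of the GFP library, and at least 3 UMIs in 0.817% and 2.47%. At all UMIs the shares with at least 1 UMI were in the opposite order, at a ratio of 1.15. These shares run against the list median, and Gadd45g alone had 2035 and 1762 of the list's UMIs, so no order is read from them. Thinned shares with at least 1 UMI of the list were 31.0% and 18.1% in microglia-like cells, 80.6% and 59.8% in oligodendrocyte-like cells and 28.7% and 26.4% in endothelial cell-like cells. For the mature list the thinned shares in astrocyte-like cells were 35.8% and 37.9%, with ratio 0.944 (interval 0.864 to 1.03).

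In astrocyte-like cells the genes of the interferon response, antigen presentation and reactive astrocyte lists were lower in the NeuroD1 library. The reactive astrocyte list had a median of -1.60 (-2.56 to -0.80), below every one of 10000 random lists, with 20 of 28 members at least 1.5-fold lower and 0 higher. Only 7 of these 28 members reached 25% of their highest class. Complement C4b was at 51.3 and 708 CPM, 13.8-fold lower (interval 12.6 to 15.2), and the protease inhibitor Serpina3n was at 12.99 and 212 CPM, 16.3-fold lower (interval 13.6 to 19.6). Gfap, the astrocyte intermediate filament, was at 1889 and 2711 CPM. Interferon response genes had a median of -3.45 (-4.21 to -2.35) with 26 of 27 members lower, among them Ifit3 at 8.91 and 168 CPM and Isg15 at 2.04 and 73.5 CPM. Antigen presentation had a median of -1.98 (-2.97 to -0.96), with 14 of 17 members lower. Most interferon genes had higher CPM in other classes, and over members with at least 25% of their highest class the medians were -1.94 (-4.02 to -0.89) for interferon, on 4 members, and -0.96 (-1.65 to -0.23) for antigen presentation, on 3 members. The astrocyte identity list had a median of 0.02 (-0.46 to 0.25), with Glul, glutamine synthetase, 2.05-fold higher and the water channel Aqp4 at 0.511 times the GFP library. The Notch and BMP target list had a median of 0.02 (-0.95 to 0.52), with Hes5, a Notch effector, at 344 and 90.1 CPM. By the size rule the genes with the largest higher ratios were the neuropeptide Gal and the hormone Sct. They had 579 and 562 UMIs against 0 and 0 and were at least 39.05-fold and 37.9-fold higher. Cpne9, Cacng5, Eps8l1, Aldh1a1, Hes5, Slco2a1, Rasgef1c and Etnppl followed. The largest lower ratios were GFP, then Gh with 7 and 436 UMIs, 250-fold lower (interval 120 to 625), then Cxcl5, Serpina3n, Ifit3b, C4b, Osmr, Gabra2, Lgals3bp and Col11a2. Different clusters held most of the class in the libraries: clusters 5 and 12 held 1616 and 814 cells of the NeuroD1 library and 137 and 9 of the GFP library, cluster 9 held 152 and 747, and cluster 2 held 1088 and 1254. In cluster 2 alone the interferon median was -2.47, on cells with medians of 805.5 and 860 UMIs against 2465.5 and 1150 in the class. Thinned to 500 UMIs the class median was -2.82. Among lists that also follow handling and RNA quality, immediate early genes had a median of -1.07 (15 of 23 lower), or -0.45 in cluster 2. Ribosomal protein genes had -0.09, mitochondrially encoded genes -0.14 and oxidative phosphorylation genes 0.55.

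Microglia-like cells of the NeuroD1 library had more RNA of homeostatic genes and less of disease-associated genes. The homeostatic list had a median of 1.31 (1.21 to 1.57), with 21 of 24 members at least 1.5-fold higher. The purinergic receptor P2ry12 was at 5765 and 2484 CPM and Tmem119 at 1955 and 503 CPM. The disease-associated list, genes that rise in microglia around plaques, had a median of -1.78 (-2.93 to -1.13), with 27 of 35 members at least 1.5-fold lower and 3 higher. Cst7, a cystatin, was at 48.2 and 1466 CPM, 30.4-fold lower (interval 25.4 to 36.7), and the lipid carrier Apoe at 2590 and 28630 CPM, 11.1-fold lower (interval 10.8 to 11.3). Interferon response genes had a median of -2.29 (24 of 30 lower), and antigen presentation genes, including H2-D1 at 984 and 5008 CPM, a median of -1.12 (15 of 19 lower). The inflammatory cytokine list went both ways, with a median of 0.59 (-0.88 to 1.13): Tnf was 3.01-fold and Il1a 4.06-fold higher while Il1b was at 64.2 and 246 CPM. The lysosome list had a median of -0.08 (-0.57 to 0.18). Crybb1, Soga1, Upk1b, Siglece, Clcf1 and Bank1 had the largest higher ratios, and Ctse, Ftl2, Igf1, Baiap2l2, Gpnmb and Cxcl13 the largest lower ones. Thinned to 500 UMIs per cell, the log2 ratios of Siglece, Bank1 and Gpnmb moved from 3.02, 3.06 and -6.53 to 2.28, 2.32 and -4.48. Different clusters held most of the class: cluster 3, led by Cst7 and Lpl, had 4 and 2149 cells and cluster 13, led by Il1a and Tnf, 675 and 69, while cluster 11, led by Il1b, had 12 and 816. In cluster 6, led by Tmem119 with 528 and 622 cells, the medians were 0.61 for the homeostatic, -0.47 for the disease-associated, -1.44 for the interferon and -0.48 for the cytokine list. Cells of cluster 6 had medians of 1353.5 and 852 UMIs, against 1811 and 1316.5 in the class. Lists that also follow handling and RNA quality moved in the same class: immediate early genes had a median of 1.24 (20 of 25 higher; 0.10 in cluster 6), ribosomal protein genes -1.22 (34 of 41 lower; -1.13), mitochondrially encoded genes -0.64 (5 of 8 lower; -0.87) and oxidative phosphorylation genes -0.78 (22 of 32 lower; -0.23).

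**Figure D3:**
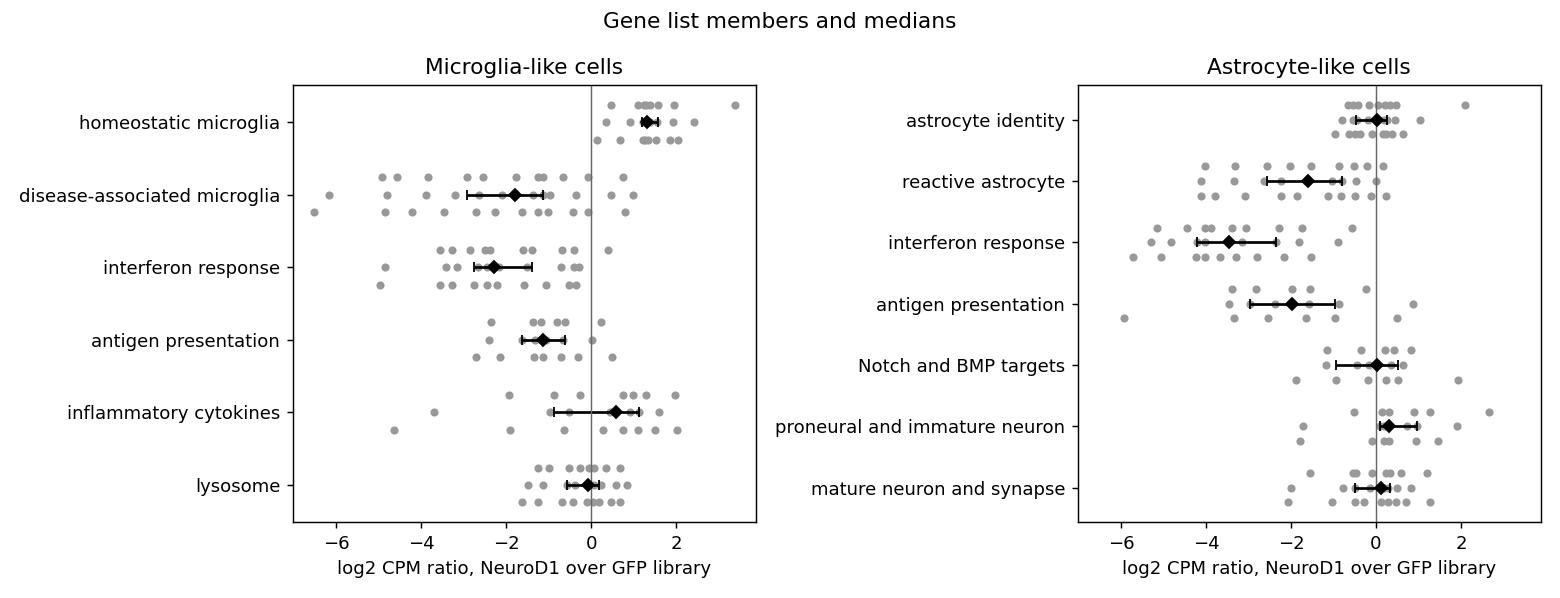
Log2 CPM ratio (NeuroD1 over GFP library) of each list member in microglia-like (left) and astrocyte-like cells (right), with members as grey points and the list median with its 95% order-statistic interval over members in black. The homeostatic microglia median was 1.31 and the disease-associated microglia median -1.78.

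Oligodendrocyte-like cells, the myelinating glia, had most myelin genes within 1.5-fold and lower immune genes. The myelin list had a median of 0.19 (-0.14 to 0.44), above 98.83% of random lists. Of its 26 members 6 were at least 1.5-fold higher, among them Mbp at 10960 and 6836 CPM, and 1 was lower. Interferon response genes had a median of -2.53 (21 of 23 lower) and antigen presentation genes -2.65 (12 of 14 lower), but only 2 and 0 of these members reached 25% of their highest class. The disease-associated oligodendrocyte list had a median of -0.55 (-1.99 to -0.24), with C4b at 121 and 799 CPM. Cholesterol synthesis genes were higher, with a median of 0.66 (0.48 to 0.84), 14 of 24 members at least 1.5-fold higher and 0 lower, including Hmgcs1 at 194 and 114 CPM. In astrocyte-like cells the cholesterol list had a median of 0.41 (0.22 to 0.69), and in microglia-like cells -0.24 (-0.73 to 0.15), or 0.49 in cluster 6. Npsr1, a neuropeptide receptor, had 0 and 378 UMIs and was at least 326-fold lower. Eps8l1, Dnah14, Rsrp1, Fam83d, Apln and Fam169a had the largest higher ratios, and Slpi, Acy3, Glns-ps1 and Serpina3n were among the largest lower ones. Thinning moved Dnah14, Fam83d and Fam169a from log2 ratios of 3.63, 2.87 and 2.96 to 1.96, 4.03 and 1.67. Clusters 0 and 16 held 2493 and 463 cells of the NeuroD1 library and 38 and 3 of the GFP library, and cluster 1, led by Gstp1 and Npsr1, held 126 and 2233. In cluster 1 the medians were -1.35 for interferon and -0.96 for antigen presentation. The 126 cells of the NeuroD1 library there had a median of 988 UMIs, against 2940 in the class.

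Endothelial cell-like cells had close levels of barrier genes, and activation genes whose direction differed with the clusters compared. The endothelial activation list had a median of 0.77 (0.18 to 1.98), with 10 of 20 members at least 1.5-fold higher, including Vcam1, a leukocyte adhesion receptor, at 368 and 158 CPM, and Lcn2 and the chemokine-binding Ackr1, each at 13.1 CPM in the GFP library, at 186 and 246 CPM in the NeuroD1 library. Without cluster 26, which is led by Lrg1, Ackr1 and Lcn2, the activation median reversed to -0.24, Vcam1 was at 136 and 150 CPM, and Ackr1 and Lcn2 were 5.33-fold (interval 2.65 to 12.5) and 3.26-fold (interval 1.89 to 6.07) higher. The cells left are mostly of cluster 4 in the NeuroD1 library and of cluster 7 in the GFP library. In cluster 7 alone, which both libraries share, the activation median was 0.71. Cells of the NeuroD1 library there had a median of 793 UMIs, against 2249 in the class. Over the whole class, cluster 26 included, the 16 members with at least 25% of their highest class had a median of 1.12. The barrier and transport list had a median of 0.13 (-0.17 to 0.39), with Cldn5, a tight junction gene, at 2846 and 3193 CPM. Interferon response genes had a median of -0.26 (-0.56 to -0.04), with 8 of 28 members lower, antigen presentation genes -0.70 (-1.60 to -0.35) and cholesterol synthesis genes 0.46 (0.16 to 0.71). Alas2, a haem synthesis gene, had 276 and 0 UMIs, and the haemoglobin gene Hba-a1 had 62213 and 71 UMIs in the same cells, so red blood cell RNA moves with it. Clusters 4 and 26 held 1742 and 85 cells of the NeuroD1 library and 115 and 1 of the GFP library, and cluster 7 held 208 and 896. Rsrp1, Lrg1 and Fam212a also had large higher ratios, and Grcc10, Maff, Osgin1, Ybx3, Ifit2 and Apold1 the largest lower ones, and thinning moved Ackr1 from a log2 ratio of 4.19 to 5.46 and Grcc10 from -2.33 to -1.71.

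In neuron-like cells the immediate early genes, which respond within minutes to stimulation and to dissociation, had a median of 1.58 (0.58 to 2.36), or 2.75 (1.08 to 4.78) over the 6 members with at least 25% of their highest class. Within cluster 18, whose cells express Reln, Fos was at 2422 and 168 CPM, 14.5-fold higher (interval 8.57 to 26.6). Mature neuron and synapse genes had a median of -1.01 in neuron-like cells and proneural genes 0.94, in a class whose clusters differ between libraries as given above. Immature neuron-like cells had a proneural median of 0.31 (-0.03 to 0.47). Outside microglia-like cells, given above, immediate early genes had medians of 0.73 in border macrophage or monocyte-like cells, 0.09 in mural cell-like cells, 0.06 in oligodendrocyte-like cells, 0.03 in endothelial cell-like cells, -1.07 in astrocyte-like cells (-0.45 in cluster 2) and -1.64 in choroid plexus epithelium-like cells. In the last 2 classes none of the 23 members reached 25% of its highest class, with at most 21.0% and 15.4%. Mitochondrially encoded genes had a median with its interval below 0 in 7 of 8 classes, with medians of -2.46 (-2.92 to -1.72) in neuron-like cells (7 of 7 members lower) and -0.75 in oligodendrocyte-like cells (-0.18 in cluster 1), while astrocyte-like cells had -0.14 (-0.75 to 0.33), or 0.04 in cluster 2. Genes of oxidative phosphorylation had medians of 1.04 in neuron-like and 0.55 in astrocyte-like cells. Cytosolic ribosomal protein genes had a median with its interval below 0 in 6 of 8 classes, from -1.22 in microglia-like and -0.70 in choroid plexus epithelium-like cells to -0.26 in oligodendrocyte-like cells, where it reversed to 0.03 in cluster 1. Their median was -0.09 (-0.33 to 0.07) in astrocyte-like and 0.58 in neuron-like cells. The median log2 ratio over genes with at least 50 UMIs was -0.13 in astrocyte-like, 0.35 in microglia-like, -0.32 in choroid plexus epithelium-like, 0.16 in endothelial cell-like and 0.38 in neuron-like cells.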

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

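The tests of sex and of a missing Thy1-driven transgene, with the minimum of 20 cells that the latter requires, were chosen only after the result was seen; the free RNA test was chosen before. Differences between classes in this part were not tested, as there is 1 library per group.

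The Y-linked Ddx3y was at 69.6 CPM in the NeuroD1 library and 0.057 CPM in the GFP library, while Xist was at 0.039 and 105 CPM, a signal outside the comparisons that separates the libraries. The ND1 feature (0 UMIs) and Neurod1 in astrocyte-like cells (ratio 2.37, interval 0.572 to 21.0) do not check the labels. In astrocyte-like cells with a GFP UMI Neurod1 ran the way the labels say, at 4.84 CPM (6 UMIs) in the NeuroD1 library and 1.04 CPM (2 UMIs) in the GFP library, with an interval of that ratio of 0.833 to 47.2. Within the NeuroD1 library Neurod1 was 3.92 times as high in cells with a GFP UMI (interval 1.22 to 11.1) and 4.87 times against depth-matched cells (interval 1.16 to 23.5). The proneural list median of that contrast was 0.69 (-0.65 to 1.37, 14 members), above 100% of random lists. In the GFP library it was 0.04 (-0.2 to 0.5, 8 members), above 64.42%. These list medians rest on unlike numbers of members and of cells with a GFP UMI (225 and 1343), so they are not weighed here. The Neurod1 values run against an exchange of the labels if Neurod1 in such cells comes from the vector, which 6 UMIs do not settle, so a mislabelled library stays open. Haemoglobin genes made up 0.462% of UMIs in the NeuroD1 library and 0.001% in the GFP library. Immediate early genes had a median log2 ratio of 1.58 in neuron-like cells and -1.64 in choroid plexus epithelium-like cells, where every one of the 23 members was at 15.4% or less of its highest class. Genes of oxidative phosphorylation had a median of 1.04 in neuron-like and -0.78 in microglia-like cells.

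Disease-associated genes were lower in microglia-like cells of the NeuroD1 library, with a median log2 ratio of -1.78. Free RNA from other cells is argued against only for the 26 members with at least 25% of their highest class. Their median was still -1.31 (-3.19 to -0.97). That level was pooled over both libraries, and microglia-like cells had 2509590 UMIs in the NeuroD1 library and 5594365 in the GFP library. Members high in the GFP library thus passed more easily, so the size of this median is not read. Sex and group cannot be told apart, because each library holds RNA of 1 sex (Ddx3y at 0.057 CPM in the GFP library), so a difference between male and female 5xFAD mice stays open beside the vector, as does untested handling (immediate early median 1.24 in the same cells). Mice of the NeuroD1 library without the Thy1-driven transgenes of 5xFAD also stay open: Thy1 UMIs per Snap25 UMI in cluster 24 were 0.0234 times those of the GFP library (interval 0.0151 to 0.0362), but that cluster had 7 cells in the NeuroD1 library, in which Slc17a7 and Camk2a were 0.190 and 0.188, App 0.241, Syt1 0.582, Nrgn 1.38, Snap25 1.66 and Thy1 itself 0.0388 times as high. In cluster 18, led by Reln, Thy1 was at 260 and 275 CPM.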

How the results depend on the processing

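The shared-cluster, left-out cluster, denominator, total without abundant genes and 1 CPM alternatives were chosen only after the result was seen. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible. Each result was counted once per alternative, so the same result can count several times. Of the named genes' values 265 stayed within their interval and 59 moved, with no change of direction. Of list medians 846 stayed, 38 moved and 5 reversed. Of class shares 56 stayed, 23 moved and 2 reversed. A value counts as reversed only where the reported interval excludes no difference. Where that interval held no difference, another 45 list medians, 4 shares of cells with neuronal RNA and 1 class share changed side, counted the same way. Among them were cytokines (-0.48) and cholesterol synthesis (0.49) in microglia-like cells and p53 (-0.20) in endothelial cell-like cells, all in 1 shared cluster. The cause was not tested for the following.

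With at least 500 genes per cell the share ratio was 1.39 for astrocyte-like and 0.266 for microglia-like cells, and the oxidative phosphorylation median in mural cell-like cells reversed to -0.06. With at most 10% mitochondrial UMIs the microglia-like ratio was 0.255 and the neuron-like ratio reversed to 1.22. The microglia-like ratio was 0.257 with doublets kept, 0.254 at resolution 0.5 and 0.385 with libraries clustered apart. As shares outside choroid plexus, microglia-like and unnamed cells, ratios were 1.07 for astrocyte-like and 0.555 for neuron-like cells and reversed to 0.865 for oligodendrocyte-like cells. With the class median set to 0 the homeostatic median was 0.96. In 1 shared cluster medians were 0.61 (homeostatic), -0.47 (disease-associated), -1.35 (interferon, oligodendrocyte-like), and reversed to 0.03 (ribosomal, oligodendrocyte-like) and -0.04 (heat shock, microglia-like). In the NeuroD1 library each shared cluster held cells with a lower median of UMIs than its class. Over members with at least 25% of their highest class the interferon median in astrocyte-like cells was -1.94, and the p53 median in choroid plexus reversed to 0.33. Without cluster 26 the endothelial activation median reversed to -0.24. Without thinning, proneural share ratios reversed to 1.15 (1 UMI) and 1.70 (3 UMIs), and mature ones changed side to 1.25 and 2.35. Thinning moved the GFP ratio to 0.00437.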

Other observations

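The tests of vector GFP in other classes, of the ND1 feature and of depth-matched cells were chosen only after the result was seen; the others were written before their values were seen, and the idea for Gh came from its difference between the libraries.

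Mural cell-like cells, the pericytes and smooth muscle of vessels, had the acute phase genes Saa2 (123 and 2 UMIs) and Saa1 (135 and 5 UMIs) among the largest higher ratios in the NeuroD1 library, with Uchl1, Rgs4 at 3241 and 942 CPM and the clock gene Dbp at 317 and 86.6 CPM; Ybx3, Gadd45g, Fgl2, Wtip, Atp5l and Dctn1 had the largest lower ones. Border macrophage or monocyte-like cells had Cd74, the MHC class II chaperone, at 2305 and 391 CPM (log2 ratio 2.55, or 3.75 thinned and 3.33 as a mean over cells) and Ccl12 at 2025 and 9004 CPM. In an unnamed cluster, 21, 22 of 122 cells of the GFP library carried 4614 GFP UMIs and 20 of 60 cells of the NeuroD1 library carried 34279 Hba-a1 UMIs. Of 2697 genes measured in all 8 classes, 2 were at least 2-fold higher in each (Ddx3y, Rsrp1) and 7 lower (Xist, GFP, Gm10689, Gm15459, Rpl17-ps3, Rpl17-ps10 and Gm45660). Processed copies of genes minus their parents had a median log2 ratio of -0.26 in astrocyte-like cells (143 pairs) and -0.56 in microglia-like cells (160 pairs).

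Vector GFP was 140-fold lower in astrocyte-like cells of the NeuroD1 library. Library depth could not lower GFP there, since its astrocyte-like cells were the deeper ones (medians of 2466 and 1150 UMIs). The depth test therefore decides nothing further: with every cell at 500 UMIs the share of cells with GFP was 0.0237 times as high (0.0171 to 0.0320). Transduced cells named to another class are argued against only where they kept GFP RNA, since GFP over all kept cells was 0.00828 times as high. Cells in which the GFAP promoter became inactive would not be counted. Vector dose or the reading of the construct cannot be told apart from group, as the ND1 feature had 0 UMIs. A hypothesis is that Gh UMIs come from the vector, for example from a growth hormone polyadenylation signal: in the GFP library Gh was at 225 CPM in astrocyte-like cells with a GFP UMI and 2.95 CPM in those without (ratio 76.2, interval 25.9 to 371), and the NeuroD1 library had 6 and 1 UMIs. The vector sequences are not given in the sources used here, so Gh may follow GFP by another route.

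The 225 astrocyte-like cells with a GFP UMI in the NeuroD1 library may carry Neurod1 RNA: its CPM was 3.92 times that of cells without (interval 1.22 to 11.1), on 6 and 13 UMIs. Their proneural list median was 0.69, above all random lists but with an interval of -0.65 to 1.37. Igfbpl1 was 5.23-fold (24 and 39 UMIs) and Tubb3 5.76-fold (21 and 31 UMIs) higher, and Rnd2 was at 0.513. Among all astrocyte-like cells of this library, 10 cells held 58 of the 63 Igfbpl1 UMIs. Whether a few cells carry the list median was not tested. Against depth-matched cells the list median was 0.74 (-0.68 to 1.5), also above all random lists. Depth as the whole cause is argued against, since matching changed the members' log2 ratios by a median of 0.0 (-0.37 to 0.11) where depth needed -0.55. Their astrocyte identity median was -0.33 (-0.55 to -0.13), and depth alone is argued against by -0.27 (-0.48 to -0.10) in matched cells, a size that also lies above the -0.5 set beforehand as the bound for no loss. The shift was not limited to neuronal genes. Without depth matching, the interferon median of these cells was 0.44 (0.16 to 1.23), above 98.03% of random lists. The reactive astrocyte median was 0.15 (-0.45 to 1.03) and the mature neuron median 0.15 (0.0 to 0.71). In the GFP library cells with over without a GFP UMI gave 0.04 for the proneural and -0.04 for the identity list. Other lists moved there: the reactive astrocyte median was -0.40 (-0.63 to -0.13) and the interferon median -0.26 (-0.45 to 0.04), the latter above 0.02% of random lists. Neurod1 had 2 UMIs with and 0 without a GFP UMI (interval of the ratio from 0.0991), too few to show whether a Neurod1 contrast is absent there.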
